A study of Mus musculus with 30 samples.

How the data were processed

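Lymphocytes from the spleens of male C57Bl/6 mice aged 6 to 10 weeks were measured on 30 arrays, in 10 groups of 3, per the labels. CD4 and CD8 T cells were each measured fresh and after culture with IL-2 alone (4 ng/ml), with IL-2 and IL-4 (10 ng/ml), or with IL-2 and IL-12 (5 ng/ml). B cells were measured fresh and after culture with anti-IgM (10 ug/ml) and IL-4 (10 ng/ml). The group and a letter were read from each array's title. The longer description of the T-cell arrays names B cells beside the T-cell subset; each array was treated as the subset in its title. What the letter stands for, and any stimulus of the T cells other than the cytokines, are not given in the sources used here. A culture time of 72 hours is written in the experiment files of 4 arrays. Nothing in the labels says that the arrays of a group came from separate mice or cultures, so p-values measure only the spread between these arrays, which may be technical.

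The authors deposited 1 intensity per probe set and array, on a linear scale with 1 decimal, from a custom Affymetrix array of glycan-related genes. The array type is named in the experiment files. The program that summarised the probe pairs into an intensity, its version and its scaling between arrays are not given in the sources used here. The 752 probe sets held values from 1 to 69827.5, and the median signal per array ran from 115 to 204. Array medians differed, so the arrays were not quantile-normalized. No detection call was used, so a signal at the low end of the range is not shown to lie above background, and the number of arrays limits the precision.

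Left out of the comparisons were 6 control probe sets for beta-actin and Gapdh, which leaves 746. Probe sets carry transcript accessions and no gene names. Names came from a RefSeq gene table of the mouse assembly GRCm38.p6, and coordinates of that table were not used. Of 462 probe sets with a RefSeq accession 449 matched, and 1 more matched through a synonym, so 450 probe sets stand for 375 named genes and 296 stay unnamed. Suffixes that mark probes shared between transcripts or families occur in 223 (_s_at) and 16 (_x_at) of the tested probe sets, and their signal can include a related transcript. For 75 of the named genes there is more than 1 probe set. A gene is represented by the probe set with the highest mean over all arrays, and no other probe set of a named gene passed the threshold in the opposite direction.

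Values were transformed as log2(signal + 16), a scale that understates the changes of dim genes. One linear model of 10 group means was fitted to all 30 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 20 residual degrees of freedom before moderation. Each contrast was tested two-sided, and a probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the 746 probe sets. Errors of log2 changes are moderated standard errors (SE), and signals are given as mean with SD between arrays. Activated T cells are the mean of the 3 cultured groups of a subset (9 arrays) against its fresh group (3 arrays), and fresh T cells are the mean of both fresh subsets. No group was cultured without a cytokine or stimulus, so activation and culture as such cannot be told apart. The difference of activation effects between cell types was tested as an interaction. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

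Genes are named by a rule. It takes, per comparison, up to 10 highest and 10 lowest log2 changes among genes past the threshold whose groups do not overlap in any array and whose higher group has a mean above the median of all tested probe sets (7.32 on the log2 scale, a signal of 143.6). Non-overlap was not asked of interactions. Further, 26 genes of glycosylation and lymphocyte surface biology were fixed by name, of which 9 are measured here. The rule also takes up to 4 members of each gene list, those with the largest absolute change. Of 33 fixed gene lists, 19 have at least 3 measured genes and were tested: sialyltransferases, sialic acid synthesis and activation, fucosyltransferases, galactosyltransferases, N-glycan precursor and transfer, nucleotide sugar synthesis, Siglecs, selectins and their ligand proteins, carbohydrate sulfotransferases, glycosaminoglycan chain synthesis, proteoglycan core proteins, glycolipid synthesis, lysosomal glycosidases and sulfatases, T-cell effector cytokines and chemokines, cytokine and chemokine receptors, lymphocyte activation markers, and markers of B cells, myeloid cells, and platelets and endothelium. The other lists have fewer measured genes and were not tested as lists. A pair of genes that the rule takes is not reported here, nor are counts of lists in which either passed. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted within each comparison, with fry and with camera at an estimated correlation beside it. The groups, tests, rule, lists and a first set of alternative settings were fixed before the data were examined.

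That first set held a pseudocount of 1 or 64, centring of each array on its median, quantile normalization, leaving out the dimmest 40% of probe sets, 1 value per gene, fitting only the groups of a comparison, an intensity trend with robust eBayes, scan day as a block, the title letter as a fixed or random block, leaving out each array in turn, and camera with an estimated correlation. Chosen after seeing the data were the 3'/5' signal ratio of the control probe sets as a covariate, leaving out both fresh T-cell arrays of letter C, leaving out both arrays whose experiment files carry each other's codes, a block of 5 scan periods, and centring on the brighter 50% of probe sets. Scan periods join the 9 scan days that lie less than 40 days apart. Where a period holds arrays of both sides of a comparison, probe sets called by limma on the arrays of the other periods were read on its own arrays, a check also chosen after seeing the data. Of the 5 arrays of the last period, 5 are marked as a retry in their experiment files. Other splits of the arrays were counted, with at most 100 drawn at random (seed 2005).

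The pipeline was tested on 20 simulated data sets with 200 of the 746 probe sets changed. At a log2 change of 2 it recovered 93.7% of them in activated against fresh CD4 cells, 93.6% in CD8 cells and 85.0% in B cells, and 92.6% in B against T cells. At a log2 change of 1 it recovered 54.1%, 54.3%, 40.4% and 48.4% in the same order. For a cytokine added to IL-2, recovery at a log2 change of 2 lay between 83.0% and 87.0%, and at 1 between 37.5% and 40.8%. Between fresh CD8 and CD4 cells it was 82.7% at a log2 change of 2. For the interactions it was 77.6% (CD8 minus CD4) and 77.8% (B minus T). The simulated noise was independent between probe sets and held no scan periods. The adjusted threshold is stricter where fewer probe sets change. These values may therefore overstate recovery for an added cytokine, where 0 to 6 probe sets passed in the real data.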

Results

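The study concerns the activation of mouse T lymphocytes and the genes that build and read their surface glycans, per its title. RNA of CD4 and CD8 T cells and of B cells from the spleen was hybridised to a custom array of genes for glycosyltransferases, glycan-binding proteins, cytokines and their receptors. Each of the 10 groups has 3 arrays: fresh CD4 and fresh CD8 cells, each subset cultured with IL-2, with IL-2 and IL-4 or with IL-2 and IL-12, fresh B cells, and B cells cultured with anti-IgM, which engages the antigen receptor, and IL-4. Pearson correlations of log2 signals between arrays of a group lay between 0.841 and 0.937, with the lowest among fresh CD4 cells. The first principal component held 33.4% of the variance between arrays.

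Control probe sets at both ends of the beta-actin (Actb) and Gapdh transcripts differed between fresh and cultured cells. The 3'/5' signal ratio of Actb was 1.90 ± 2.15 (SD, n = 9) on fresh arrays and 0.984 ± 0.0677 (SD, n = 21) on cultured arrays, and that of Gapdh was 1.73 ± 1.23 and 0.816 ± 0.0723. A single fresh CD4 array, of title letter C, had ratios of 7.62 and 4.97, without which the fresh arrays averaged 1.18 ± 0.185 and 1.33 ± 0.237 (SD, n = 8). The fresh CD8 array of the same letter had 1.62 for both genes. The median signal of all probe sets was 175 ± 28.2 (SD, n = 3) in fresh CD4 cells against 125 ± 8.54 after culture with IL-2 and IL-4.

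**Figure D1:**
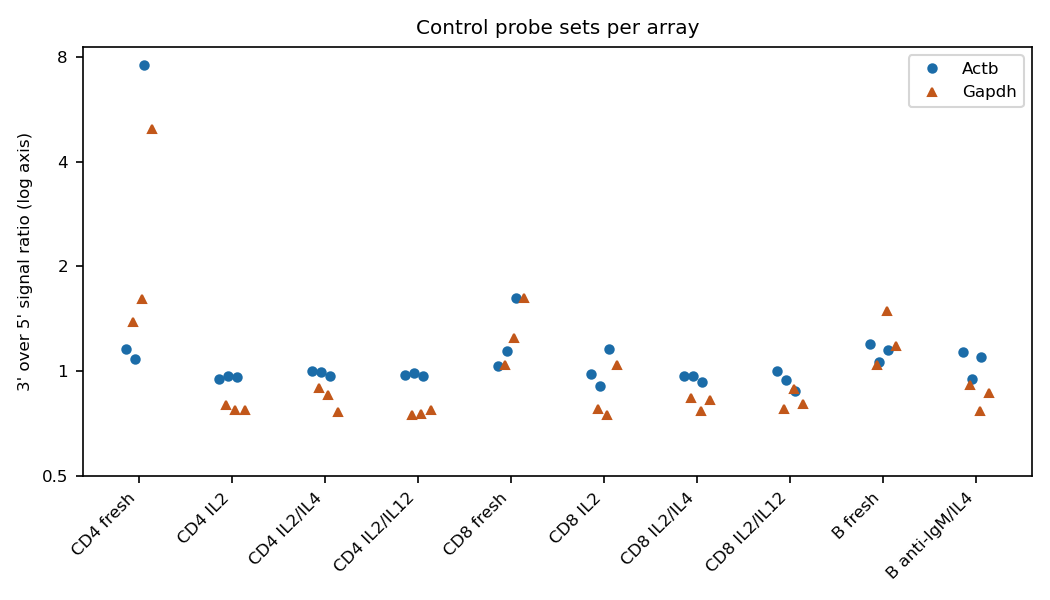
Ratio of 3' to 5' signal of the Actb and Gapdh control probe sets on each of the 30 arrays, by group, on a log axis. A single fresh CD4 array stands at 7.62 (Actb) and 4.97 (Gapdh), while the 21 cultured arrays averaged 0.984 and 0.816.

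Culture of CD4 T cells with IL-2, alone or with IL-4 or IL-12, was compared with fresh CD4 cells to find the genes of the array that differ with activation. Il12rb1, a chain of the IL-12 receptor, rose from a signal of 125 ± 80.1 (SD, n = 3) to 5160 ± 1308 (SD, n = 9), a log2 change of 5.31 ± 0.41 (SE; limma adjusted p = 4.87e-10). The inflammatory chemokine genes Ccl4 (4.45 ± 0.33) and Ccl3 (4.29 ± 0.44) rose with it, as did the costimulatory receptor gene Tnfrsf4 (4.34 ± 0.42) and the gene of its ligand, Tnfsf4 (3.35 ± 0.36). Further rises were those of the other IL-12 receptor chain Il12rb2 (3.58 ± 0.30), Tnfsf8 (3.26 ± 0.26), the cytokine gene Il4 (3.11 ± 0.36), the galectin gene Lgals7 (2.94 ± 0.33) and the glycolysis gene Aldoa (2.91 ± 0.28). Itgax, an integrin chain of dendritic cells, fell from 1651 ± 490 to 34.4 ± 11.1, 33.0-fold lower with a limma adjusted p of 2.64e-08. Vcam1, an adhesion molecule of endothelial and stromal cells, fell by 4.47 ± 0.36 on the log2 scale. Lower too were Siglece (-2.90 ± 0.50), a sialic acid-binding receptor of myeloid cells, the B-cell IgE receptor gene Fcer2a (-2.72 ± 0.34), and Kit (-2.60 ± 0.34), Cxcl9 (-2.03 ± 0.34) and Il10ra (-1.56 ± 0.23). For each of these genes all 9 cultured arrays lay on one side of all 3 fresh arrays.

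In all, 161 of the 746 probe sets passed the threshold in this comparison, 76 higher and 85 lower, and they stand for 39 higher and 43 lower named genes and 68 unnamed probe sets. Over all 746 probe sets the arrays of the groups did not overlap in 128 (17.2%), where chance gives 0.909%, and 115 of these are among the 161. With scan period as a block 119 passed, 111 of them among the 161. With the 3'/5' ratio as a covariate 101 passed, 83 of the 161 kept their call and 3 turned direction, and with scan day as a block 80 passed, 71 were kept and 1 turned. A single period holds both kinds of array, 1 fresh and 2 with IL-2 and IL-4. Of 123 probe sets called on the arrays of the other periods, 117 had the same direction there, at a median 0.792 times the size, and no period does so for IL-2 alone or IL-12. The median log2 change over all probe sets was -0.13, and after centring each array on its median it was 0.18, so directions are relative to an unstated scaling. Centring kept 130 of the 161, and 68.4% of its calls were higher, against 47.2% without it.

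Among genes that make glycans, members of the lists moved in both directions in CD4 cells. Of 4 sialyltransferases 2 rose, St8sia1 (2.06 ± 0.40), the synthase of the ganglioside GD3, and St6galnac4 (1.17 ± 0.26), and 1 fell, St3gal6 (-1.05 ± 0.30; limma adjusted p = 0.0116). The St3gal6 arrays overlapped between groups, and its adjusted p was 0.0524 without the fresh array of letter A and 0.149 with median centring. Of 3 genes of sialic acid synthesis and activation 1 rose, Slc35a1 (0.94 ± 0.20), the transporter of activated sialic acid. Of 3 genes of N-glycan precursor synthesis and transfer 2 rose, Canx (1.97 ± 0.27), which encodes the glycoprotein chaperone calnexin, and Dpm2 (1.15 ± 0.23), a subunit of the enzyme that makes dolichol-linked mannose. Of 5 genes of nucleotide sugar synthesis 2 rose, Gpi1 (1.43 ± 0.22) and Hk1 (1.33 ± 0.22), which also act in glycolysis. Of 14 carbohydrate sulfotransferases 2 fell, the heparan sulfate enzymes Hs3st1 (-1.69 ± 0.39) and Hs6st1 (-1.18 ± 0.19). Of 5 glycolipid genes 1 rose, which was St8sia1 again. With the 3'/5' ratio as a covariate the calls of St8sia1 (1.66, adjusted p = 0.0566), St6galnac4 (0.52), St3gal6 (adjusted p = 0.141), Slc35a1 (0.81), Dpm2 (0.75), Hk1 (0.57) and Hs3st1 (-0.89) ended, and with scan day as a block those of St3gal6, Slc35a1, Dpm2, Hs3st1 (-0.43) and Hs6st1. The adjusted p of Hs3st1 was also 0.0777 with scan period as a block, and Slc35a1 was 0.48 (adjusted p = 0.0980) with 1 value per gene. None of the 23 measured fucosyltransferases, galactosyltransferases, selectins with their ligands, genes of glycosaminoglycan chains and proteoglycan cores passed in limma, and 0 had an unadjusted p under 0.05.

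Of the fixed genes, Cmah, which hydroxylates sialic acid, had a log2 change of -0.86 ± 0.43 in CD4 cells that did not pass (limma adjusted p = 0.159). Without the fresh array of letter C it was -1.46 (adjusted p = 0.0266), and with the 3'/5' covariate -2.01 (adjusted p = 0.00919). Selplg, the selectin ligand protein PSGL-1, stood at -0.31 ± 0.24, at -0.68 (adjusted p = 0.0426) without that array, at -0.90 (adjusted p = 0.000348) with quantile normalization and at 0.0096 with median centring. Gcnt1, Mgat3, Fut7 and C1galt1 did not pass, with log2 changes from -0.070 to 0.32.

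T-cell effector cytokines and chemokines rose as a list in CD4 cells: 5 of 16 rose, among them Ccl4, Ccl3 and Il4, and 1 fell (camera adjusted p = 0.0173). With an estimated correlation the camera adjusted p was 0.0504. The median log2 change of the list was 0.45, 0.70 with scan period as a block and 0.79 within the shared scan period. Of 21 cytokine and chemokine receptors 2 rose, both chains of the IL-12 receptor, and 7 fell, among them Ccr2 (-1.84 ± 0.48) and Cxcr5 (-1.77 ± 0.44). The adjusted p of Ccr2 was 0.0529 without the fresh array of letter A, and that of Cxcr5 0.0576 without that of letter C, 0.0649 with scan period as a block and 0.184 with the 3'/5' covariate (-1.36). With scan day as a block Ccr2 stood at -2.55 (0.0795) and Cxcr5 at -1.53 (0.160), both no longer past the threshold. Of 4 lymphocyte activation markers 1 rose, Tnfrsf4. The N-glycan precursor list, with 3 of its 31 genes measured, also shifted upward (median 1.15, camera adjusted p = 0.0173). Its median was 0.88 under the scan period block and 0.72 within the shared period. Its adjusted p was 0.186 with an estimated correlation, and without the dimmest 40% of probe sets 0 lists passed with camera.

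Markers of other cells were read in the CD4 arrays too. Of 4 B-cell markers 3 fell, Fcer2a, Cxcr5 and the B-cell Siglec Cd22 (-1.26 ± 0.26), and the list had a median change of -1.52 (camera adjusted p = 0.0246). The list's adjusted p was 0.186 with an estimated correlation, 0.0720 without the fresh array of letter A, and 0.0509 with scan period as a block (median -1.26; -1.52 within the shared period). Cd22 stood at 1142 in fresh CD4 cells, 478 in cultured CD4 cells and 11323 in fresh B cells. Of 4 Siglecs 2 fell, Siglece and Cd22, of 3 myeloid markers 1 fell, again Siglece, and of 4 platelet and endothelial markers 1 fell, the platelet factor Pf4 (-1.76 ± 0.47). Neither of the last lists passed (camera adjusted p of 0.729 and 0.650), and the myeloid markers Siglec1 and Cd33 both stood at 0.06. The call of Pf4 ended without the fresh array of letter C (limma adjusted p = 0.0809), with scan period as a block (0.0833) and with the 3'/5' covariate (0.391). The covariate also ended the calls of Cd22 (0.0596) and Cxcr5, 2 of the 3 called B-cell markers, and scan day as a block those of Siglece (-1.72; 0.218) and Pf4. Adjusted over the list alone, the list counts given above for CD4 cells stayed except that 3 genes of the N-glycan precursor list, 7 effector genes and 4 receptors rose.

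In CD8 T cells the same comparison gave rises of Ccl3 from 49.1 ± 32.5 (SD, n = 3) to 3841 ± 1368 (SD, n = 9), a log2 change of 5.89 ± 0.44 (SE; limma adjusted p = 1.56e-10), and of Tnfrsf4 (5.13 ± 0.42), Il12rb1 (5.12 ± 0.41), Il12rb2 (5.09 ± 0.30) and Ccl4 (4.75 ± 0.33). Higher as well were the integrin chain gene Itgav (3.56 ± 0.34), the growth factor gene Vegfa (2.93 ± 0.37) and the lymphotoxin gene Lta (2.64 ± 0.35). Among genes of sialic acid, Cmah fell from 607 ± 242 to 71.3 ± 64.7 (8.03-fold lower; limma adjusted p = 5.38e-06) and St3gal6 fell from 981 ± 309 to 184 ± 51.9 (4.96-fold lower; adjusted p = 1.57e-06). Itgae, the CD103 integrin chain, fell from 2714 ± 641 to 264 ± 50.8 (9.70-fold). The chemokine receptor Cxcr3 (-3.29 ± 0.50), the chemokine Ccl5 (-2.69 ± 0.42), Vcam1 (-3.95 ± 0.36) and Itgax (-3.59 ± 0.50) were lower too, with all 9 cultured arrays on one side of all 3 fresh arrays for each gene named here.

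For CD8 cells 155 probe sets passed, 77 higher and 78 lower, in 38 higher and 41 lower named genes, and the groups did not overlap in 140 of the 746 (18.8%; chance gives 0.909%), 122 of them among the 155. A block for scan period left 164, 145 of them among the 155. Within the 2 shared periods, with 1 and 2 fresh against 1 and 5 cultured arrays, 110 of 112 and 50 of 52 probe sets called on the other arrays had the same direction, at a median 1.03 and 0.784 times the size. After median centring 131 of the 155 were kept, the median of all probe sets moved from -0.07 to 0.13, and 60% of the calls were higher against 49.7%.

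Among glycan genes of CD8 cells, members of the lists again moved both ways. Of 4 sialyltransferases 1 fell, St3gal6, and 1 rose, St6galnac4 (0.73 ± 0.26; limma adjusted p = 0.0424), a call that ended without any 1 array except the IL-2 array of letter L and the IL-4 array of letter C (adjusted p up to 0.220, without the fresh array of letter B), and with the 3'/5' covariate (0.49; 0.167), quantile normalization (0.0519) or a pseudocount of 1 (0.0522). Of 3 sialic acid synthesis genes 1 fell, Cmah. The selectin ligand gene Selplg fell (-1.11 ± 0.24). Of 14 carbohydrate sulfotransferases 2 fell, Hs6st1 (-1.02 ± 0.19) and Papss1 (-0.99 ± 0.29), which makes the sulfate donor, and of 14 lysosomal enzymes 3 fell, among them Manba (-0.86 ± 0.22) and Ctsa (-0.78 ± 0.25). Papss1 had an adjusted p of 0.106 without the fresh array of letter A and 0.0503 without that of letter B, and median centring ended the calls of Papss1 (0.107), Manba (0.0920) and Ctsa (0.239). Ctsa was also lost without the fresh array of letter A (0.177) or B (0.126) and with scan period as a block (0.0545), and scan day as a block ended the calls of Manba (-0.58; 0.125) and Ctsa (-0.64; 0.137). Of 4 genes of glycosaminoglycan chains 1 rose, Extl1 (1.69 ± 0.40). Of 3 N-glycan precursor genes 2 rose, Canx (1.41 ± 0.27) and Dpm2 (1.02 ± 0.23); the list's median change was 1.02 with a camera adjusted p of 0.0635. None of the 30 measured fucosyltransferases, galactosyltransferases, nucleotide sugar, proteoglycan and glycolipid genes, and myeloid, platelet and endothelial markers passed in limma, and 6 had an unadjusted p under 0.05. Fixed genes that did not pass were Gcnt1, Mgat3, Fut7 and C1galt1, with changes from -0.34 to 0.20.

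Effector genes of CD8 cells rose as a list: 6 of 16 rose, among them Ccl3, Ccl4 and Lta, and 2 fell, among them Ccl5 (median 0.35; camera adjusted p = 0.0324). Its adjusted p was 0.126 with an estimated correlation, 0.0623 without the fresh array of letter A and 0.0532 without that of letter C, and 0.0523 after median centring. The median was 0.47 with scan period as a block, and 1.27 and 0.53 within the shared periods. Of 21 receptors 4 rose, among them Il12rb1 and Il12rb2, and 6 fell, among them Cxcr3 and Cxcr5 (-2.28 ± 0.44). Of 4 activation markers 1 rose, Tnfrsf4. Of 4 B-cell markers 3 fell, Cxcr5, Fcer2a (-1.98 ± 0.34) and Cd22 (-1.54 ± 0.26), the last being the only 1 of 4 Siglecs to pass. The B-cell list shifted downward (median -1.76; camera adjusted p = 0.0236), with an adjusted p of 0.154 with an estimated correlation and 0.0623 without the fresh array of letter A. With scan period as a block its median was -1.73 (adjusted p = 0.0336), and within the shared periods -2.88 and -1.27. Adjusted over the list alone, the list counts given above for CD8 cells stayed except that 8 receptors and 4 B-cell markers fell.

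**Figure D2:**
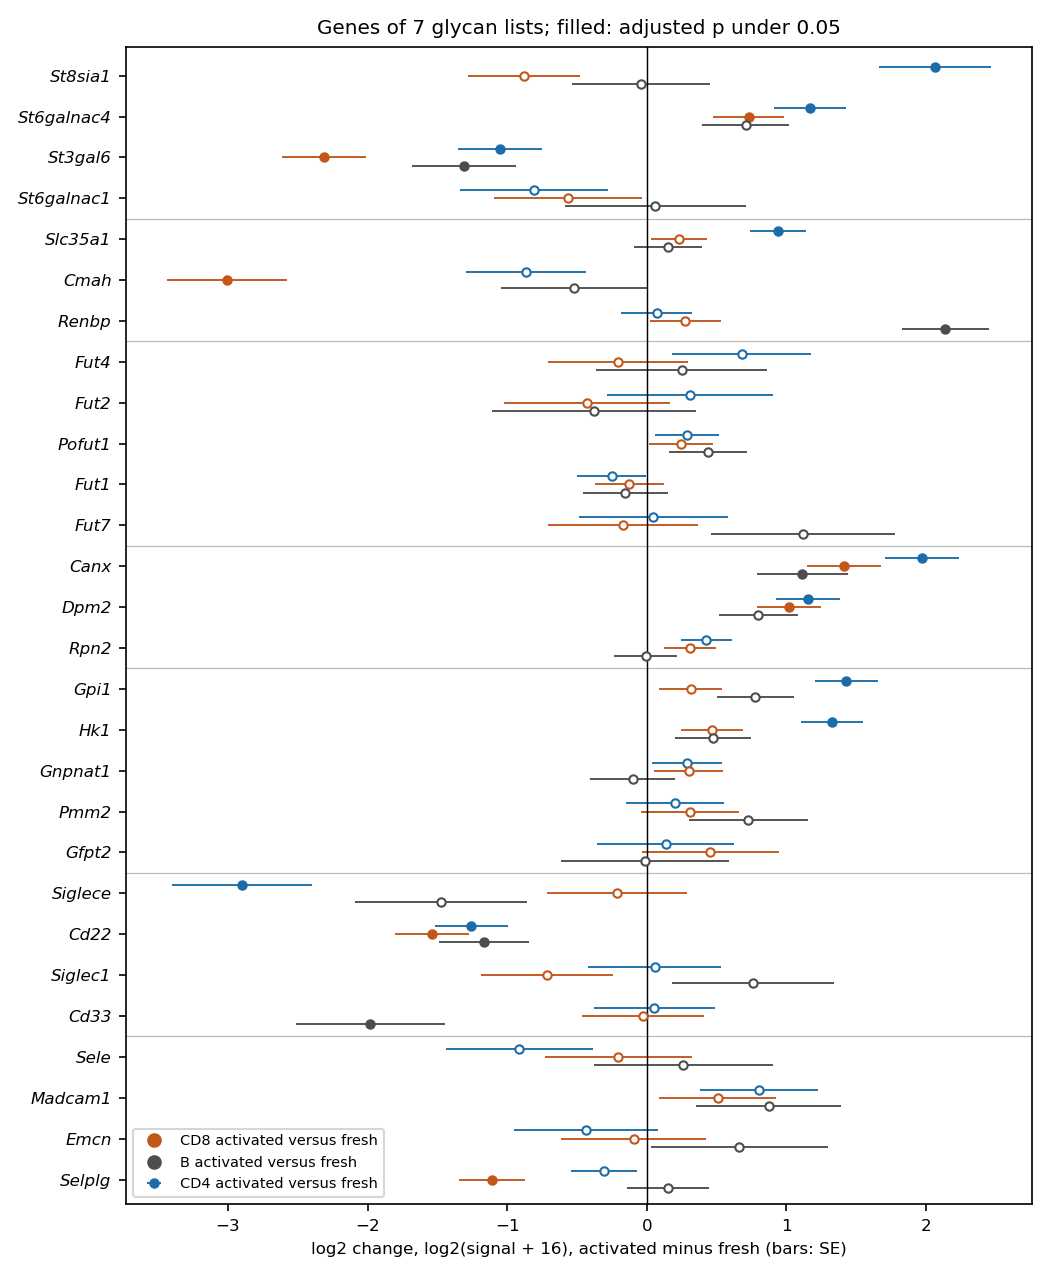
Log2 change with its standard error of measured genes of 7 lists (sialyltransferases, sialic acid synthesis, fucosyltransferases, N-glycan precursor, nucleotide sugar synthesis, Siglecs, and selectins with their ligands) in cultured against fresh CD4, CD8 and B cells; filled points have a limma adjusted p under 0.05. Cmah stands at -0.86, -3.01 and -0.52, and Canx at 1.97, 1.41 and 1.11, in that order.

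In B cells cultured with anti-IgM and IL-4, against fresh B cells, Renbp rose from 718 ± 71.8 to 3238 ± 581 (SD, n = 3 each). This gene of an epimerase of N-acetylglucosamine and N-acetylmannosamine had a log2 change of 2.14 ± 0.31 (SE, limma adjusted p = 3.95e-05). The surface molecule genes Cd83 (2.02 ± 0.28) and Cd70 (2.66 ± 0.53), the chemokine Ccl4 (2.07 ± 0.40) and the sterol gene Msmo1 (1.92 ± 0.39) rose, with no overlap between arrays. Ltb, a lymphotoxin chain, fell from 22680.4 ± 1861 to 2046 ± 234, 11.0-fold lower (limma adjusted p = 5.25e-10), and Vcam1 (-3.42 ± 0.43), Ccr2 (-3.07 ± 0.58), Il10ra (-2.42 ± 0.29) and Lta (-2.22 ± 0.42) fell as well. Cd22 fell by 1.17 ± 0.32 and St3gal6 by 1.31 ± 0.37 on the log2 scale. Without 1 array the calls of Cd22 (adjusted p up to 0.122; fresh E, activated G or H) and St3gal6 (up to 0.142; fresh E, activated H or K) ended. Quantile normalization ended the call of Cd22 (-0.81, adjusted p = 0.127) and median centring that of St3gal6 (0.0582). Cmah, Selplg, Mgat3, Fut7 and C1galt1 did not pass, nor did Gcnt1 (-1.36 ± 0.49; limma adjusted p = 0.0822), which was -2.22 (adjusted p = 0.000417) without the fresh array of letter K and passed with a pseudocount of 64 (0.0357).

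In B cells 73 probe sets passed, 25 higher and 48 lower, and of 164 probe sets without overlap between groups (22%; chance gives 10%) 65 are among them. Without 1 array the count ran from 41 (activated array of letter H) to 81 (fresh array of letter K). A scan period block gave 90, with all 73 among them. Each of the 3 shared periods holds 1 fresh and 1 activated array, where 33 of 36, 30 of 31 and 69 of 85 probe sets called on the other arrays had the same direction, at a median 0.968, 0.989 and 0.536 times the size. Quantile normalization put 47.3% of the calls on the higher side against 34.2%. When the fit held only the B-cell arrays, 23 passed, and Cd70 (adjusted p = 0.183), Ccl4 (0.0830), Msmo1 (0.0845), Cd22 (0.186) and St3gal6 (0.142) no longer did.

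By list, 1 of 3 sialic acid synthesis genes rose in B cells (Renbp), 1 of 4 sialyltransferases fell (St3gal6), 2 of 4 Siglecs fell (Cd33, -1.98 ± 0.53, and Cd22), and 1 of 3 N-glycan precursor genes rose (Canx, 1.11 ± 0.33). Of 16 effector genes 1 rose (Ccl4) and 3 fell (Ltb, Lta and Ccl5, -1.82 ± 0.52). Of 21 receptors 1 rose (Il12rb1, 1.82 ± 0.51) and 3 fell (Ccr2, Il10ra and Ifngr1, -1.49 ± 0.27). Among markers, 1 of 4 for B cells (Cd22), 1 of 3 for myeloid cells (Cd33) and 1 of 4 for platelets and endothelium (Pf4, -1.98 ± 0.58) fell. Calls that ended without 1 array were those of Canx and Ccl5 (adjusted p up to 0.134 and 0.160; fresh G or E, activated G or K), Il12rb1 (up to 0.178; fresh G or E, activated G or H), Cd33 (up to 0.101; fresh E, activated G or H) and Pf4 (up to 0.134; fresh E or K, activated G or H). The fit of the B-cell arrays alone ended these calls and that of Ifngr1 (adjusted p up to 0.252), and scan day as a block those of Pf4, Cd33, Cd22, Canx, Ccl5 and Il12rb1 (0.0544 to 0.276). The title letter as a fixed block ended those of Cd33, St3gal6, Ccl5 and Il12rb1. With 1 value per gene Pf4 stood at -1.02 (0.163) and Ccl5 at -0.86 (0.223), and median centring left Canx at 0.0828. None of the 58 genes in the 9 lists without a call passed in limma, and 12 had an unadjusted p under 0.05. No list passed with camera (adjusted p of 0.117 for lysosomal glycosidases and sulfatases). Adjusted over the list alone, 2 N-glycan precursor genes, 1 nucleotide sugar gene, 1 glycosaminoglycan gene, 2 lysosomal genes and 2 activation markers rose, and 3 Siglecs, 3 B-cell markers and 2 myeloid markers fell; the other counts were as over all genes.

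Some genes passed in the same direction in all 3 cell types. Canx, Ccl4, Il12rb1, Msmo1, Tnfsf8 and Ybx1 were higher in CD4, CD8 and B cells after culture (10 probe sets), and Cd22, Cxcl9, Il10ra, Il11ra1, Itgax, Itgb7, Ltb, Sipa1, St3gal6 and Vcam1 were lower (19 probe sets). The size of the change differed in tests of the difference between B and T cells for Il12rb1 (-3.40), Ccl4 (-2.53), Tnfsf8 (-1.35; limma adjusted p = 0.0152), Il10ra (-1.12; 0.0271), Ltb (-2.17) and Itgax (2.19), and between CD8 and CD4 cells for Tnfsf8 (-1.75) and Ltb (-1.04; 0.0444). In B cells the call of Il11ra1 ended without fresh array G (0.0813) or activated array H (0.0707), beside those of Canx, Il12rb1, Cd22 and St3gal6 given above. Each comparison has its own fresh arrays. CD4 and CD8 cells shared 50 higher and 46 lower probe sets, where independent lists of these sizes would share 7.84 and 8.89. CD4 and B cells shared 12 higher and 26 lower (2.55 and 5.47 for independent lists), and CD8 and B cells 12 and 24 (2.58 and 5.02). In the opposite direction, 4 probe sets called higher in CD4 cells and 5 called higher in CD8 cells were called lower in B cells, and 0 were called opposite between CD4 and CD8 cells.

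Each cytokine condition was also set against the fresh cells of its subset. In CD4 cells Il12rb1 rose by 5.07 ± 0.51 with IL-2, 5.69 ± 0.51 with added IL-4 and 5.16 ± 0.51 with added IL-12, and Itgax fell by 4.86 ± 0.61, 5.28 ± 0.61 and 4.99 ± 0.61 on the log2 scale. Il4 rose with IL-2 and IL-4, from 29.9 to 1829 (log2 5.35 ± 0.44; limma adjusted p = 2.93e-09), where Cmah fell by 2.09 ± 0.52. The protease inhibitor gene Timp1 rose with IL-2 and IL-12 in CD4 cells (3.34 ± 0.55) and in CD8 cells (4.12 ± 0.55), where the cytokine gene Il10 also rose (3.24 ± 0.36). In CD8 cells Ccl3 rose by 5.50 ± 0.54, 5.91 ± 0.54 and 6.24 ± 0.54 in the same order, and Cmah fell by 3.51 ± 0.52, 3.37 ± 0.52 and 2.14 ± 0.52. The counts were 128 (IL-2), 158 (with IL-4) and 117 (with IL-12) in CD4 cells and 120, 135 and 109 in CD8 cells, of which 59, 73, 61, 55, 64 and 53 were higher. With scan period as a block they were 90, 129, 84, 129, 140 and 115. Scan day as a block left 44, 31 and 59 in CD4 cells, and ended the calls of Cmah with IL-4 in CD4 cells (-3.02; adjusted p = 0.0567) and with IL-12 in CD8 cells (-1.46; 0.172). Fitting only the arrays of a comparison left 62, 86 and 63 in CD4 cells and 89 with IL-4 in CD8 cells, with Cmah at 0.0535 in CD4 cells. Within shared periods of 1 or 2 arrays a side, probe sets called on the other arrays had the same direction in 64 of 67 for CD4 cells with IL-4, and in 26 of 26 (IL-2), 83 of 86 and 38 of 39 (IL-4) and 36 of 37 (IL-12) for CD8 cells, while CD4 cells with IL-2 or IL-12 share no period with fresh CD4 cells. Median centring raised the share of higher calls in each of the 6, from 46.1% to 64.2%, 46.2% to 71.3% and 52.1% to 68.1% in CD4 cells and from 45.8% to 60.6%, 47.4% to 62.9% and 48.6% to 61% in CD8 cells. It moved the medians of all genes from -0.11, -0.19 and -0.10 to 0.12, 0.24 and 0.20, and from -0.09, -0.11 and -0.09 to 0.13, 0.10 and 0.07.

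Adding IL-4 to IL-2 gave few calls in CD4 cells. Il4 itself rose from 228 ± 136 to 1829 ± 386 (SD, n = 3 each), a log2 change of 3.03 ± 0.44 (limma adjusted p = 0.000135), and the chemokine receptor gene Ccr4 rose from 78.4 ± 102 to 390.0 ± 70.8 (2.63 ± 0.41; adjusted p = 0.000331). Cmah fell from 303 ± 26.5 to 48.3 ± 30.3 (-2.40 ± 0.52; adjusted p = 0.0176). In all 6 probe sets passed, 4 higher and 2 lower, and 66 had an unadjusted p under 0.05. The groups did not overlap in 133 of the 746 probe sets (17.8%, where chance gives 10%). With scan period as a block 4 passed. The shared period holds 1 array with IL-4 and 2 without, where all 4 probe sets called on the other arrays had the same direction, at a median 0.604 times the size. The Cmah call ended without any 1 array except that of letter B with IL-4 (adjusted p up to 0.157), and after quantile normalization (0.0861) and after median centring (-2.20; 0.0734), which raised the median of all genes from -0.03 to 0.18 and left only higher calls (100%; 80% after quantile normalization; 66.7% without scaling). Fitting only the 6 arrays left adjusted p values of 0.0889 for Il4 and Cmah and 0.245 for Ccr4, and scan day as a block 0.0900 for Il4 (2.56) and Cmah (-2.99) and 0.173 for Ccr4 (2.61).

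Adding IL-12 to IL-2 raised Timp1 in CD4 cells from 59.4 ± 14.4 to 619 ± 257 (SD, n = 3 each; log2 2.99 ± 0.55; limma adjusted p = 0.0111), the only probe set to pass, with 28 at an unadjusted p under 0.05. It passed also with scan period as a block. Its change was 1.13 times the pooled one in a shared period of 2 arrays a side and 0.733 times in one of 1 array a side, and these arrays also entered the call. Its call ended without 1 array in 4 of the 6 fits (adjusted p up to 0.154; IL-2 arrays E or L, IL-12 arrays D or E) with a pseudocount of 1 (0.0524) and when only these arrays were fitted (0.105). In CD8 cells IL-12 raised the chemokine receptor gene Cxcr6 from 349 ± 116 to 1337 ± 112 (1.94 ± 0.37; limma adjusted p = 0.00771), and 1 unnamed probe set passed with it (43 unadjusted). Both passed with scan period as a block (3 in all). Their changes were at a median 0.895 and 1.16 times the pooled ones in the 2 shared periods, where the side with IL-12 has 1 array and which also entered the calls. Of the calls 66.7% were higher after quantile normalization, against 100%. The Cxcr6 call ended without 1 array in 3 of the 6 fits (adjusted p up to 0.0938; IL-2 array L, IL-12 arrays H or L), when only these arrays were fitted (0.242) and with scan day as a block (0.107). It ended too with the title letter as a fixed block. Adding IL-4 to IL-2 gave 0 probe sets past the threshold in CD8 cells with limma, with 28 at an unadjusted p under 0.05, and 0 with scan period as a block.

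**Figure D3:**
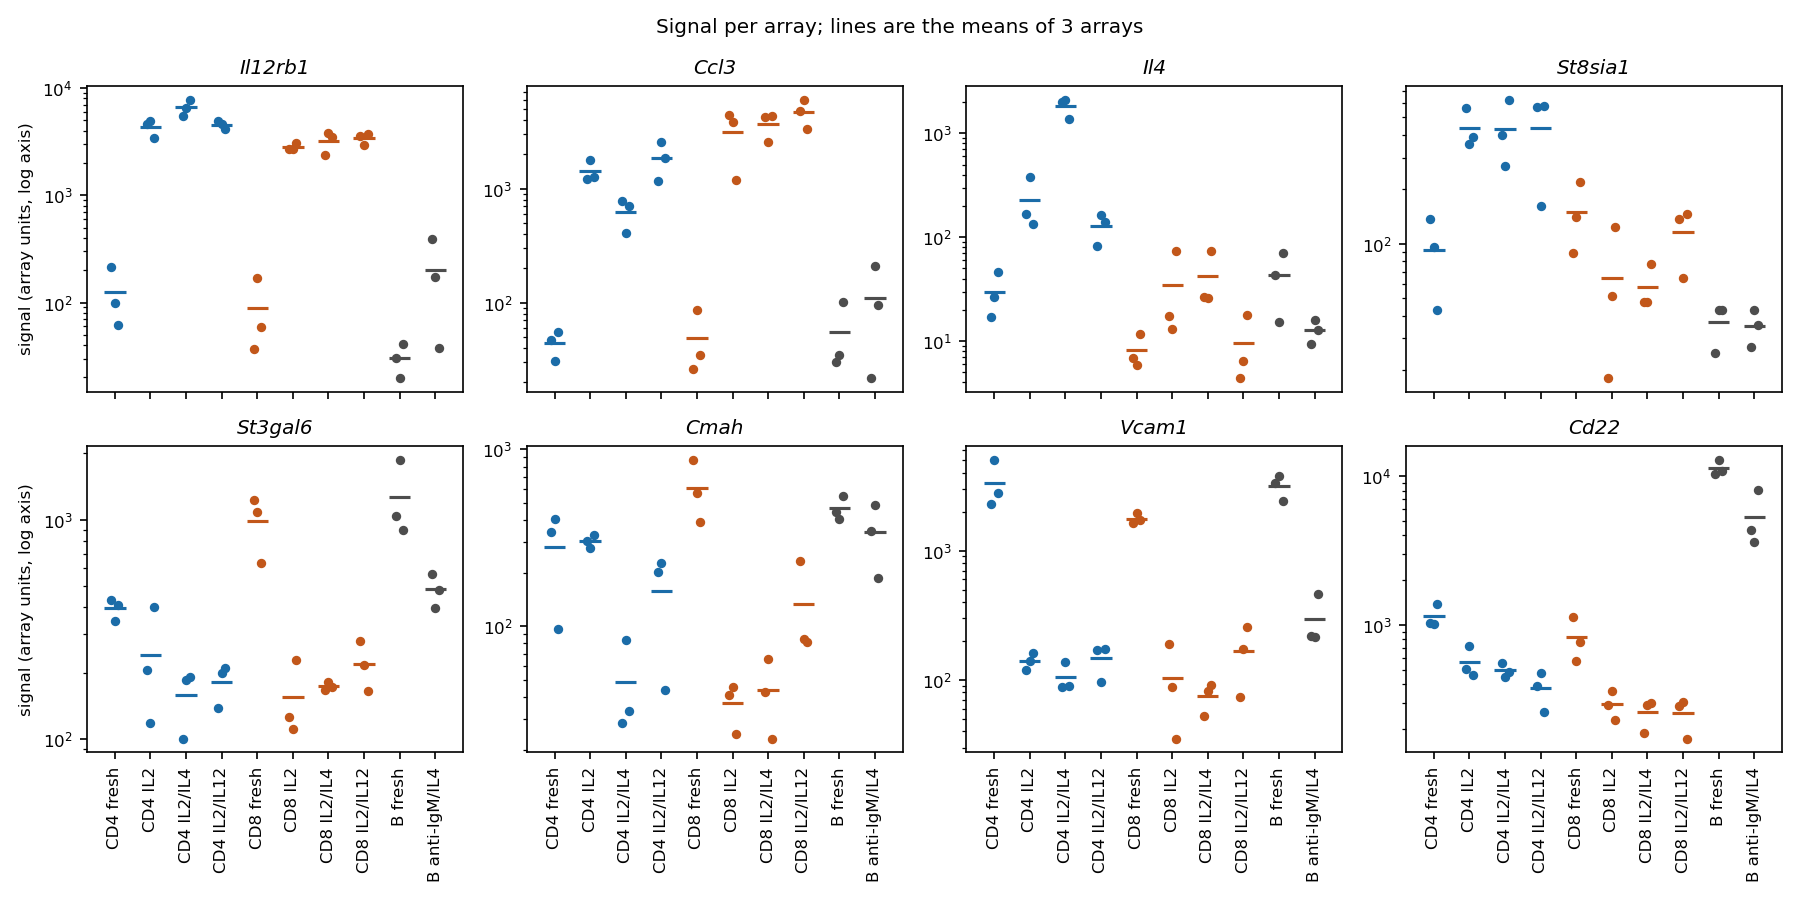
Signal of 8 genes on each array, by group, on a log axis, with lines at the mean of the 3 arrays. Il12rb1 and Ccl3 lie higher in cultured than in fresh T cells, Il4 reaches a mean of 1829 in CD4 cells with IL-4, and St3gal6, Vcam1 and Cd22 lie lower in cultured cells.

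Fresh CD8 and CD4 cells differed in Itgae, at 2714 ± 641 against 448 ± 96.1 (SD, n = 3 each; log2 2.55 ± 0.30; limma adjusted p = 7.13e-06), and in the lectin-like receptor gene Klrd1 (2.23 ± 0.43; adjusted p = 0.00560), both higher in CD8 cells. The death ligand gene Fasl (-1.41 ± 0.31; adjusted p = 0.0157), the chemokine receptor gene Ccr8 (-1.98 ± 0.48) and the chemokine gene Cxcl10 (-1.48 ± 0.36) were lower in CD8 cells (adjusted p = 0.0304 for both). In all 12 probe sets passed, 4 higher and 8 lower, and 88 had an unadjusted p under 0.05. With scan period as a block 9 passed, 7 of them among the 12, with Fasl (-1.42; adjusted p = 0.0586), Ccr8 (-2.16; 0.0793) and Cxcl10 (-1.19; 0.210) no longer past. In the shared period, of 1 array a side, 7 of 8 probe sets called on the other arrays had the same direction, at a median 0.435 times the size. Without 1 array the count ran from 5 (CD8 array of letter B) to 13, and the calls of Ccr8 and Cxcl10 each ended without any 1 array except the CD8 array of letter C (adjusted p up to 0.283 and 0.193) and that of Fasl in 2 (up to 0.0611; CD4 array A, CD8 array B). The median of all genes moved from -0.08 to 0.11 with median centring, 0.03 with quantile normalization and 0.03 with centring on the brighter probe sets, and the share of higher calls from 33.3% to 57.1% with median centring, which ended the calls of Fasl (0.0719) and Cxcl10 (0.0893). The 3'/5' covariate ended those of Ccr8 (0.0888) and Cxcl10 (0.0950). Scan day as a block left 3 and ended the calls of these genes except Itgae, and fitting only the 6 arrays left 0 by limma (61 unadjusted), with Itgae at 0.0830 and Klrd1 at 0.0872.

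Fresh B cells differed from fresh T cells in genes of their lineage. The B-cell markers Fcer2a (3.56 ± 0.36), Cd22 (3.55 ± 0.28) and Cxcr5 (2.83 ± 0.47) were higher, Cd22 at 11323 ± 1289 (SD, n = 3) against 984 ± 284 (SD, n = 6) with a limma adjusted p of 8.03e-10. So were the heparan sulfate sulfotransferase Hs3st1 (3.73 ± 0.41), Cd83 (2.41 ± 0.24), Ccr6 (1.93 ± 0.35) and Renbp (1.30 ± 0.27). The IL-7 receptor gene Il7r was lower in B cells, at 258 ± 123 against 7561 ± 1532 (29.7-fold; limma adjusted p = 3.12e-11), as were Cxcr6 (-2.96 ± 0.32), Cxcr3 (-2.74 ± 0.53), Il2rb (-2.60 ± 0.44) and Selplg (-2.04 ± 0.25). In all 61 probe sets passed, 27 higher and 34 lower. The arrays of the groups did not overlap in 72 of the 746 (9.65%; chance gives 2.38%), 46 of them among the 61. Scan day as a block left 32 (30 of the 61), and fitting only these arrays 32 (31 of the 61). With scan period as a block 63 passed, 56 of them among the 61. Within the 3 shared periods, with 1 B-cell array against 2, 1 and 1 T-cell arrays, 35 of 36, 41 of 43 and 54 of 67 probe sets called on the other arrays had the same direction, at a median 0.874, 0.843 and 0.568 times the size. Gcnt1, which branches O-glycans, was higher in B cells (1.66 ± 0.43; adjusted p = 0.0122) with overlapping arrays, and its call ended without the B-cell array of letter G (0.123) or E (0.168), when only these arrays were fitted (0.169), with scan day as a block (1.01; 0.431) and with 1 value per gene (0.63; 0.230). Cmah, Mgat3, C1galt1, St3gal6 (0.96 ± 0.32; limma adjusted p = 0.0643) and Fut7 (-1.60 ± 0.57; 0.0861) did not pass. Quantile normalization (adjusted p = 0.0260), a pseudocount of 64 (0.0285) and leaving out the dimmest 40% (0.0410) put St3gal6 past the threshold, and scan period as a block (-1.91; 0.0443) or a fit of only these arrays (0.0442) did so for Fut7.

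As lists, B-cell markers were higher in B than in T cells (3 of 4; median 3.19; camera adjusted p = 1.74e-07), the single list call that held with an estimated correlation (adjusted p = 0.00253). Their median was 3.12 with scan period as a block and 2.75, 3.68 and 2.41 within the shared periods. Siglecs were higher too (2 of 4, Cd22 and Cd33, 2.04 ± 0.46; median 1.29; camera adjusted p = 0.0163), with an adjusted p of 0.108 with an estimated correlation, 0.0987 with scan period as a block (median 1.05; 0.38, 1.63 and 0.53 within periods), 0.0683 without the B-cell array of letter E and 0.0533 without that of letter K. Of 3 sialic acid synthesis genes 1 was higher (Renbp), of 5 selectins and ligands 1 lower (Selplg), of 14 sulfotransferases 2 higher (Hs3st1 and Chst3, 1.45 ± 0.45), of 5 glycolipid genes 1 higher (B3gnt5, 1.99 ± 0.44) and 1 lower (B4galnt1, -1.06 ± 0.28), of 14 lysosomal enzymes 2 higher (Naglu, 1.58 ± 0.49, and Hexa, 0.88 ± 0.26), of 21 receptors 3 higher and 5 lower (among them Cxcr5, Il7r, Cxcr6 and Cxcr3), of 4 activation markers 1 lower (Fas, -1.10 ± 0.24), and of 3 myeloid markers 1 higher (Cd33). Without 1 of the 9 arrays the call of Chst3 ended in 7 fits (adjusted p up to 0.360, without B array K; kept only without CD8 A or B array E), that of Naglu in 6 (up to 0.140; CD4 B or C, CD8 C, any B array), that of Hexa in 4 (up to 0.158; CD8 B or C, B arrays G or E) and that of B4galnt1 in 2 (up to 0.124; B arrays E or K). Median centring ended all 4 (0.0587, 0.0792, 0.0765 and 0.0646), scan period as a block those of Chst3 (0.107) and Hexa (0.0677), and scan day as a block, or a fit of only these arrays, all 4 with B3gnt5 and Fas. None of the 50 genes in the other 9 lists passed in limma, and 12 had an unadjusted p under 0.05. Adjusted over the list alone, the counts stayed as they were except for sialyltransferases (2 higher, 1 lower), sialic acid synthesis (2 higher), fucosyltransferases (1 lower), proteoglycans (1 higher), glycolipid synthesis (2 lower), receptors (4 higher, 7 lower) and activation markers (2 lower).

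The effect of culture differed between cell types when the difference itself was tested. The galectin gene Lgals7, whose signal went from 34.2 to 384 in CD4 cells, had a lower response in CD8 cells (difference -3.29 ± 0.47, SE; limma adjusted p = 0.000114), and so did Ccl5 (-3.20 ± 0.60), which fell in CD8 cells. So did Itgae (-2.65 ± 0.35; adjusted p = 4.57e-05), which already differed between the fresh subsets. In B cells against T cells the responses of Lta (-4.30 ± 0.49), Il12rb2 (-4.29 ± 0.43) and Ccl3 (-4.49 ± 0.63) were lower, and that of Renbp was higher (1.96 ± 0.36; limma adjusted p = 0.000546). Scan day as a block ended the calls of Lgals7 (-2.87; 0.0825) and Ccl5 (-3.40; 0.0690). Between CD8 and CD4 cells 30 probe sets passed in limma, 15 on each side, 14 of them passed with scan period as a block (15 in all) and 5 with scan day as a block (8 in all). Between B cells and T cells 88 passed, 35 higher and 53 lower in B cells, 78 of them with the block (88 in all) and 50 with scan day as a block (55 in all). After median centring 18.7% of the B minus T calls were higher, against 39.8%, and the median of all genes moved from 0.13 to -0.14 there and from 0.03 to -0.10 for CD8 minus CD4. Quantile normalization moved the B minus T median to 0.03.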

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

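The comparison of cultured CD8 with cultured CD4 cells, the block for scan period, its test on the probe sets still called and the fits without both fresh T-cell arrays of letter C were chosen only after the result was seen.

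Culture changed 30 probe sets differently in CD8 and CD4 cells, by a limma test of the difference itself, and this difference is why the genes are listed again. Lgals7, a galectin gene, had a mean signal of 34.2 in fresh CD4 cells and from 310 to 523.5 in cultured CD4 cells, against 47.5 to 91.5 in cultured CD8 cells. Its difference, CD8 minus CD4, was -3.29 ± 0.47 on the log2 scale (SE; adjusted p = 0.000114). St8sia1, the synthase of the ganglioside GD3, went from 92.1 to between 431 and 437 in CD4 cells, while CD8 cells had 150.4 fresh and from 57.8 to 115.9 cultured (-2.94 ± 0.57; adjusted p = 0.00272). The chemokine gene Ccl5 (-3.20 ± 0.60; adjusted p = 0.00213), the integrin chain Itgae (-2.65 ± 0.35; 4.57e-05), and Il4 (-2.41 ± 0.51) and Tnfsf8 (-1.75 ± 0.37), each at 0.00445, lay on the same side. So did the sialic acid hydroxylase Cmah (-2.14 ± 0.61; 0.0460), the glycolysis genes Aldoa (-1.40 ± 0.40; 0.0461) and Gpi1 (-1.11 ± 0.32; 0.0461), and the adhesion gene Icam2 (-1.33 ± 0.35; 0.0299). On the other side were Siglece (2.69 ± 0.71) and the heparan sulfate gene Extl1 (2.15 ± 0.56), both at 0.0299, the death ligand Fasl (1.68 ± 0.35; 0.00445) and Il12rb2 (1.51 ± 0.43; 0.0461). Siglece stood at 399 in fresh CD4 and 97.5 in fresh CD8 cells. Of 100 splits of the subset names within each condition 1, the real one, gave 30 probe sets or more, and the highest other gave 7. Such splits also carry the difference between subsets into the contrast, so they cannot exclude chance for the difference of responses alone.

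Several of these calls lay near the threshold and ended without 1 array, by limma adjusted p. Siglece no longer passed without the fresh CD4 array of letter B (0.0640) or C (0.0769) or the fresh CD8 array of letter B (0.133) or C (0.0917). Extl1 no longer passed without fresh CD4 B (0.124), fresh CD8 B (0.15) or fresh CD8 C (0.0613), and Icam2 without fresh CD4 C (-0.89; 0.169), fresh CD8 A (0.0889) or fresh CD8 B (0.138). The highest values for Il12rb2 (0.188), Cmah (-1.55; 0.243), Aldoa (-0.81; 0.242) and Gpi1 (-0.67; 0.214) came without fresh CD4 C. Il12rb2 kept its call only without CD4 IL-2 arrays D or E, CD4 IL-12 array E, fresh CD4 B or fresh CD8 C, and Gpi1 only without fresh CD4 A or B. Aldoa kept its call only without CD4 IL-4 array A, fresh CD4 A or B, or fresh CD8 C. Cmah kept its call only without the CD4 arrays IL-12 L, IL-4 A, fresh A or fresh B or the CD8 arrays IL-12 D, IL-4 B or fresh C. The calls of Siglece, Il12rb2, Cmah, Aldoa and Gpi1 also ended with a pseudocount of 1 and with median centring, that of Icam2 with centring (0.0913) and that of Il4 with a pseudocount of 1 (0.0692). With the 3'/5' covariate Siglece (0.0674), Il12rb2, Cmah (-1.43), Aldoa (-0.80), Icam2 (-0.86) and Gpi1 (-0.67) did not pass, and with scan day as a block the only genes of these to keep their call were Itgae and Il4. Without both fresh T-cell arrays of letter C the calls of Siglece, Extl1, Il12rb2, Cmah, Tnfsf8, Aldoa, Icam2 and Gpi1 ended, as did that of St8sia1 (-2.27; 0.0714).

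Degraded RNA on the fresh CD4 array of letter C, whose 3'/5' ratios were 7.62 and 4.97, is argued against as the whole cause of the CD8 minus CD4 difference: without that array 86.7% of the 30 probe sets were still called or kept at least 80% of their change, 18 of them called. With scan period as a block 46.7% of the 30 were still called, few enough to meet the outcome set before this test for scan period as the cause, while over the 30 the differences kept a median 97.0% of their size, so that it stays open for the set. The 14 still called, Lgals7, Ccl5, St8sia1, Itgae and Il4 among them, kept a median 109% of their difference. They were picked by their call under this block, so their size under it cannot decide on scan period. Of the 16 whose calls ended, with a median SE of 0.42 before and 0.48 after, 8 kept at least 80% of the difference, Fasl (1.69; limma adjusted p = 0.0516), Il12rb2 (1.52; 0.0578), Aldoa (-1.47; 0.171), Cmah (-1.92; 0.224) and Tnfsf8 (-1.44; 0.0795) among them, which does not speak for scan period, and 8 kept less, among them Siglece (1.69; 0.346), Extl1 (1.61; 0.346), Icam2 (-1.01; 0.255) and Gpi1 (-0.85; 0.354). Of the 30, 66.7%, or 20 probe sets, also differed between cultured CD8 and cultured CD4 cells. That met the outcome set against a different composition of the fresh preparations as the cause. The 30 were picked by a difference of responses that holds the same cultured arrays, so differences between the cultured subsets were favoured in advance. The cultured comparison also leaves out the fresh arrays, which enter the difference of responses too. It therefore cannot decide on composition or exclude a share of it for the 20. Composition stays open too for 33.3%, the 10 that differed mostly between the fresh groups. A difference between the subsets themselves, which the design names, may account for the 20 as a hypothesis, with scan period open.

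The response of B cells differed from that of T cells in 88 probe sets by the same kind of test, and as B cells were cultured with anti-IgM and IL-4 the difference covers the stimulus too. Lower in B cells were the responses of Ccl3 (-4.49 ± 0.63; limma adjusted p = 2.39e-05), Lta (-4.30 ± 0.49; 1.35e-06), Il12rb2 (-4.29 ± 0.43; 3.43e-07), Il12rb1 (-3.40 ± 0.58; 0.000355) and Tnfrsf4 (-3.38 ± 0.59; 0.00036). Also lower were those of Tnfsf4 (-2.84 ± 0.50; 0.000404), Il4 (-2.83 ± 0.51; 0.000428), Ccl4 (-2.53 ± 0.47; 0.000546), Ltb (-2.17 ± 0.29; 1.68e-05) and the sulfotransferase gene Chst12 (-2.17 ± 0.63; 0.0232). Higher were those of Cd70 (2.75 ± 0.61; 0.00353), which went from 18.7 to 323 in B cells, Tgfb3 (2.51 ± 0.80; 0.0422), Fzd4 (2.39 ± 0.61; 0.0103), Il6st (2.27 ± 0.75; 0.0490) and Itgax (2.19 ± 0.70; 0.0435). The others were Ccr9 (2.12 ± 0.48; 0.00462), Itgae (2.05 ± 0.35; 0.000282), Renbp (1.96 ± 0.36; 0.000546), Cxcr6 (1.96 ± 0.43; 0.00296) and Itga6 (1.90 ± 0.50; 0.0119). Of 100 splits 1, the real one, gave 88 or more, and the highest other gave 4. These splits do not test the difference of responses alone, so they cannot exclude chance for it.

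Among the B minus T calls, those of Fzd4 and Itga6 ended without the fresh B array of letter E (limma adjusted p = 0.0550 for both). Chst12 no longer passed without fresh B arrays G (0.109) or E (0.0556) or activated array K (0.0729). Tgfb3 no longer passed without B fresh E (0.107) or K (0.0894), activated G (0.110) or K (0.0912), CD4 IL-2 array L (0.0530), fresh CD8 C (0.0718) or CD8 IL-2 array D (0.0514). Il6st kept its call only without activated B array G, fresh B K, CD4 IL-4 B, fresh CD4 B or CD8 IL-2 arrays D or E (highest 0.226, without activated B array H). Itgax lost its call in 15 of the 30 fits, with the highest value without fresh B array K (1.20; 0.219) and then activated B array K (0.171), and none of the other 13 above 0.0711. Median centring ended the calls of Tgfb3 (0.0671), Il6st (0.0850), Itgax (0.116) and Itga6 (0.0639), scan period as a block those of Il6st (0.0956) and Itgax (0.0871), and the 3'/5' covariate those of Il6st (0.0591), Itgax (0.0525) and Chst12 (0.0524). With 1 value per gene Fzd4 stood at 0.86 (0.128). A pseudocount of 1 left Tgfb3 at 0.153 and Il6st at 0.0613, and scan day as a block ended the calls of Cd70, Tgfb3, Fzd4, Il6st, Cxcr6, Itga6 and Chst12 (0.0527 to 0.121).

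A control probe set at the 3' end of Gapdh, not among the 746 probe sets of the comparisons, was brighter in cultured than in fresh cells of every kind when tested beside them, with p adjusted over all 747. Its log2 change was 1.63 ± 0.25 in CD4 cells (limma adjusted p = 1.53e-05), 1.24 ± 0.25 in CD8 cells (0.000419) and 1.32 ± 0.30 in B cells (0.00451).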

How the results depend on the processing

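The scan period block, the 3'/5' covariate, centring on the brighter probe sets and the fits without both fresh T-cell arrays of letter C or both arrays with exchanged codes were chosen only after the result was seen. Of 306 results for genes and lists 185 kept their direction and their side of the threshold under all alternatives run for them, 113 crossed the threshold under at least 1, and 9 turned direction under at least 1. Over all alternatives 7200 values stayed, 584 lost and 13 gained the call, and 31 turned. Without 1 array the counts of the main comparisons ran from 140 to 163 (CD4 activation, 161), 128 to 159 (CD8, 155), 49 to 75 (B against T, 61), and 5 to 8 (lists, 7). Larger moves were those of B activation (41 to 81, 73 with all arrays), B minus T (58 to 92, 88), CD8 minus CD4 (14 to 34, 30), fresh CD8 against CD4 (5 to 13, 12), CD4 IL-4 against IL-2 (3 to 7, 6), and IL-12 against IL-2 in CD4 (0 to 3, 1) and CD8 cells (1 to 3, 2). The lowest of these came without activated B array H, fresh B array E, fresh CD8 array B (for both), CD4 IL-2 array L (for both) and CD8 IL-2 array L.

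Scan day as a block left 80 in CD4 activation, 44, 31 and 59 for CD4 cells with IL-2, IL-4 and IL-12 against fresh, 3 between fresh CD8 and CD4 cells, 32 between B and T cells, 8 for CD8 minus CD4, 55 for B minus T, 1 for IL-12 in CD8 cells and 0 for IL-4 in CD4 cells (limma; 30 unadjusted). Fitting only the arrays of a comparison, which leaves fewer arrays to estimate the spread, gave 23 for B activation, 62, 86 and 63 for CD4 cells with IL-2, IL-4 and IL-12, 89 for CD8 cells with IL-4, and 32 between B and T cells. In the same fits limma gave 0 for IL-4 (76 unadjusted) and IL-12 (46) in CD4 cells, IL-12 in CD8 cells (52), and fresh CD8 against CD4 (61). The 3'/5' covariate gave 101 for CD4 activation, 96 for CD4 cells with IL-4 and 4 for IL-12 in CD8 cells. Scan period as a block gave 15 for CD8 minus CD4, and 14 passed without both fresh T-cell arrays of letter C. Median centring gave 18 for CD8 minus CD4 and 7 for fresh CD8 against CD4, and a trend with robust eBayes gave 19 for the latter. A pseudocount of 1 left 0 for IL-12 in CD4 cells (limma; 25 unadjusted), and 64 gave 2 there and 4 in CD8 cells. Without the dimmest 40%, and with 1 value per gene, IL-4 in CD4 cells gave 3 and IL-12 gave 2. Without the dimmest 40% fewer genes were tested and 0 lists passed with camera (9 unadjusted); an estimated correlation left 1 of 7. Beyond these constructions the cause was not tested.

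Genes that did not pass turned sign. In CD4 activation Selplg was 0.0096 with median centring and 0.12 with scan day as a block, and Mgat3 0.25 with median centring and 0.086 with quantile normalization. In CD8 activation Gcnt1 was -0.21 with 1 value per gene and -0.034 with the scan day block, and Fut7 0.024 with median centring, 0.14 without both fresh arrays of letter C and 0.17 without the exchanged codes. Between B and T cells Cmah was -0.14 with the covariate and without letter C, and Mgat3 -0.028 with quantile normalization, -0.52 with scan day and -0.052 with scan period. Without 1 array the turned values ran from -0.11 to 0.33 (CD4 Gcnt1), -0.56 to 0.50 (CD4 Mgat3), -0.18 to 0.26 (CD4 Fut7), -0.53 to 0.14 (CD8 Fut7), -0.22 to 0.38 (B Selplg), -0.0029 to 0.47 (B against T Cmah) and -0.18 to 0.35 (Mgat3). The cause was not tested.

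The letters in the titles paired the arrays at most in part. Of 39 pairs with the same letter 9 had residuals correlated above 0.1 (r from -0.135 to 0.358, median 0.0394). Of 30 arrays 10 correlated best with their own letter, and the consensus correlation was 0.0822. The pair at 0.358 was fresh CD4 and fresh CD8 of letter C, and the only pairs of letters G, H and K stood at 0.163, 0.123 and 0.172. The share of arrays that chance would match to their own letter was not computed. With the letter as a fixed replicate block, where it could be fitted, the counts were 64 (B activation), 170 and 137 (CD4 and CD8 cells with IL-4), 27 (CD8 minus CD4), 15 (fresh CD8 against CD4), 2 for IL-12 in CD4 and 1 in CD8 cells, and Cxcr6 with IL-12 in CD8 cells (1.73; adjusted p = 0.164), Cd33, St3gal6, Ccl5 and Il12rb1 in B activation (0.0519 to 0.0873) and Extl1, Il12rb2 and Gpi1 in CD8 minus CD4 (0.0523 to 0.0824) did not pass. As a random block it gave 163, 159 and 82 for CD4, CD8 and B activation, 19 for fresh CD8 against CD4 and 2 for IL-12 in CD4 cells.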

Other observations

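The comparison of cultured subsets, the differences of cytokine effects between subsets, the shares of B-cell RNA, the 3'/5' covariate and the tests on Cmah and Timp1 were chosen only after the result was seen.

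Cultured CD8 cells were also set against cultured CD4 cells, with 9 arrays each averaged over the cytokine conditions. The chemokine gene Xcl1 (log2 4.54 ± 0.47, SE; limma adjusted p = 8.13e-08) and the lectin-like receptor gene Klrd1 (3.30 ± 0.25) were higher in CD8 cells, as were Ccl3 (1.61 ± 0.31) and Il12rb2 (1.18 ± 0.21). Lower in CD8 cells were Il4 (-3.29 ± 0.25), Lgals7 (-2.40 ± 0.24), the ganglioside gene St8sia1 (-2.30 ± 0.28), Ccl5 (-1.64 ± 0.30), the chemokine receptor genes Ccr4 (-1.63 ± 0.24) and Ccr8 (-1.59 ± 0.28), and Tnfsf8 (-1.62 ± 0.18). Each of these genes passed without any 1 of the 18 arrays (limma adjusted p up to 0.00234), with scan period as a block and after median centring. In all 72 probe sets passed, 25 higher and 47 lower, with 11 higher and 22 lower named genes, and 54 of the 72 passed with scan period as a block (59 in all). Of 100 splits of the subset names within each cytokine condition 1, the real one, gave 72 or more, the lowest share such splits can give, and the highest other gave 33. The subsets were spread differently over the scan periods and the arrays of a group may be technical, so this share does not exclude chance or a structure of the arrays.

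The effect of IL-4 differed between the subsets in 3 probe sets by limma, with 38 at an unadjusted p under 0.05. The rises of Il4 and Ccr4 in CD4 cells were absent from the CD8 calls, and the differences, CD8 minus CD4, were -2.75 ± 0.62 and -2.58 ± 0.59 (adjusted p = 0.0448 for both). Without 1 array Il4 kept its call only without CD4 arrays IL-2 E or IL-4 C or CD8 arrays IL-2 E or IL-4 C (adjusted p up to 0.255), and Ccr4 only without CD4 IL-2 array E (up to 0.258). Of 100 splits of the subset names 9 gave 3 or more and the highest gave 20, so chance is not excluded for this count; such splits also carry the difference between subsets into the contrast. For IL-12, 0 probe sets passed (30 unadjusted), all 100 splits gave as many and the highest gave 17. Cxcr6, called with IL-12 in CD8 cells, stood at 0.22 ± 0.37 in CD4 cells, and the difference of 1.73 ± 0.52 did not pass (limma adjusted p = 0.553).

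Of 18 changes of 6 markers of myeloid, platelet and stromal cells with culture, 10 were called lower, those of Itgax and Vcam1 in all 3 populations among them. The myeloid list did not pass (camera adjusted p of 0.729, 0.809 and 0.362 in CD4, CD8 and B cells). Nor did the platelet and endothelial list (0.650, 0.809 and 0.548), of whose 4 measured members only Pf4 is among the 6. Its other members were called in none of the populations. Itgax and Vcam1 are in no tested list and were already named above for their fall, so the 10 calls do not stand for such markers in general. With the 3'/5' ratio as a covariate the median change of the 6 markers (Siglec1, Siglece, Cd33, Itgax, Pf4 and Vcam1) kept 87.9% of its size, -1.64 against -1.87. That met the outcome set against RNA degradation in the fresh arrays as the cause, and Itgax and Vcam1 were still called in all 3. The median pools the 3 populations. The ratio also differed between fresh and cultured arrays and was by far the highest on 1 fresh CD4 array, so the covariate cannot exclude degradation for the set. Of the 10 calls 9 were kept. Single values moved more in CD4 cells, where Pf4 lost its call (-0.98 against -1.76, limma adjusted p = 0.391) and Siglec1, not called, went from 0.06 to 1.47. Other cells of the spleen in the fresh preparations could account for it and stay open, since over the 9 fresh arrays the markers had a mean pairwise correlation of 0.0854, at percentile 62 of 10000 random sets of 6 fallen genes (95th percentile 0.348). The markers did not move alike, with Siglec1 and Cd33 at 0.06 ± 0.47 and 0.06 ± 0.44 beside Itgax at -5.04 ± 0.50 in CD4 cells, Siglece and Cd33 at -0.21 ± 0.50 and -0.03 ± 0.44 in CD8 cells, and Siglec1 at 0.76 ± 0.58 in B cells, which goes against an equal loss of all such cells and leaves a loss of some kinds open. A response of the lymphocytes themselves was not tested.

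Of 4 B-cell markers 3, Cd22, Fcer2a and Cxcr5, were called lower in cultured than in fresh cells of each T-cell subset, and the labels of these arrays name B cells beside the subset. The list's camera adjusted p was 0.0246 in CD4 and 0.0236 in CD8 cells, and 0.186 and 0.154 with an estimated correlation. If B cells in the fresh preparations were the source, each marker would need about the same share of B-cell RNA. In CD4 cells Cd22 needed 5.87%, Fcer2a 9.0%, Cxcr5 11.2% and Cd72 14.6% of the fresh B-cell signal. The highest share was 2.49 times the lowest, which met the outcome set for B cells. The bounds of Cd72 and Cxcr5 include 0, and those of Cd22 (0.67% to 11.1%) and Fcer2a (0.59% to 17.4%) are wide. With such bounds the shares could not have gone against B cells, so B cells stay open as the source in CD4 cells. In CD8 cells the shares were 4.91% (Cd22), 6.44% (Fcer2a), 13.5% (Cxcr5) and 26.8% (Cd72), a ratio of 5.46 with bounds that include 0 for all 4, so there too the explanation stays open. A fall of these genes in T cells themselves was not tested.

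Cmah fell with IL-4 in CD4 cells (-2.40 ± 0.52) and stood at 0.13 ± 0.52 in CD8 cells, and the hypothesis that the effect differs between subsets was tested on the same data. The difference of 2.54 ± 0.74 (limma unadjusted p = 0.00223) did not pass over all probe sets (adjusted p = 0.277). Cmah was at 36.9 in CD8 cells with IL-2 alone, where a fall of this size may not be measurable, so the hypothesis stays open. Timp1 rose with IL-12 in CD4 cells, and a shared effect in CD8 cells is a hypothesis that the CD8 arrays are consistent with. There it went from 235 ± 91.9 to 899 ± 297 (SD, n = 3 each) with no overlap, a log2 change of 1.87 ± 0.55 (limma unadjusted p = 0.00249, adjusted p = 0.310). The difference between subsets was -1.12 ± 0.78 (limma adjusted p = 0.992).

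Other splits of the arrays were counted for each comparison of the report. In CD4 and CD8 activation 1 of 100 splits, the real one, gave as many probe sets (161 against a highest other of 22, and 155 against 16). Between B and T cells 1 of 84 did. These shares lie under 0.05 and are the lowest such splits can give. As the arrays of a group may be technical, they do not exclude chance between mice or cultures. Between B and T cells the highest other split gave 51 against 61. It groups fresh CD4 C, fresh CD8 C and fresh B K, the 3 fresh arrays with the highest median signals (204, 188 and 179), which points to a structure of the arrays. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. The real and highest other counts were 73 and 7 for B activation, and 128 and 2, 158 and 0, and 117 and 1 for CD4 cells with IL-2, IL-4 and IL-12 against fresh. For CD8 cells they were 120 and 1, 135 and 0, and 109 and 1. They were 6 and 0 for IL-4 and 1 and 0 for IL-12 in CD4 cells, 0 and 0 for IL-4 (all 10 splits) and 2 and 1 for IL-12 in CD8 cells, and 12 and 3 for fresh CD8 against CD4.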
